A study of Mus musculus with 2 samples.

How the data were processed

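The series holds 2 single-cell RNA libraries from lung of C57BL/6 mice aged 8 to 10 weeks, 1 of cells sorted as XCR1-positive (cDC1 library) and 1 of cells sorted as CD172a-positive (cDC2 library). Per the labels' protocols, tissue was dissociated with dispase, the libraries were made with the 10x Chromium v3.1 kit, which tags each captured transcript with a UMI, and they were multiplexed in 1 sequencing lane. The number of mice behind each library is not given in the sources used here. The authors deposited raw UMI counts per gene and barcode, 1 matrix per library. Per the submitters' processing notes, the counts come from Cell Ranger 3.2 on the mm10 genome, while per the file headers the matrices carry software version 3.0.2, and both are given because they differ. Seurat is named in the same notes without a role. The annotation release and the way barcodes were selected before deposit are not given in the sources used here. The kit counts 3' ends, so gene length plays little part in the values, and UMIs remove amplification duplicates, so counts can be treated as molecules. Of 31053 feature IDs, 30934 were matched by ID to GENCODE vM21 on GRCm38 (the same assembly as mm10), from which coordinates were taken. A further 71 features share a symbol with another, and these stayed separate.

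The deposited matrices held 2939 barcodes with 36021556 UMIs (cDC1 library) and 3045 barcodes with 39188956 UMIs (cDC2 library), with a lowest total of 503 UMIs in each. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. This removed 365 and 210 barcodes, 355 and 206 of them over the mitochondrial limit. Scrublet as built into scanpy, with an expected rate of 2.5%, then marked 4 and 2 doublets, 0.111% of 5409 cells, too few to rely on the calls. Those 6 cells were removed, and doublets otherwise stayed in. The final libraries had 2570 and 2833 cells, medians of 2615.5 and 2655 genes and of 3.91% and 3.75% mitochondrial UMIs.

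For the library comparison, UMIs were summed over cells and scaled to CPM of the library total, with exact Poisson intervals, and the ratio of CPM was given an exact conditional binomial interval. With 1 library per group no p-value or standard error can be had, and cells are not replicates. Intervals have a 95% level and cover counting error only. A gene was measured at 10 CPM or more in 1 library and called by a rule of size at 2-fold or more. A count of 0 was set to a floor of 3 counts. All cells passing the filter entered, since the sorts are the groups. A second comparison kept only cells of clusters named as dendritic. At the depth of the summed libraries, 50.02 CPM of Tlr3 in the cDC1 library rest on 1749 UMIs. The mature cells of the cDC2 library hold 944917 UMIs, so single genes rest on far fewer there.

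Before the data were examined, 30 gene lists (544 symbols, 3 not matched), markers of 19 cell types and the rule for naming genes were fixed. The lists cover cDC1 identity, cDC2 identity, shared conventional DC genes, MHC class II and class I presentation, maturation, cell cycle, Toll-like receptors, nucleic acid sensing, interferon-stimulated genes, chemokines and their receptors, cytokines and their receptors, TNF receptors, lectins and scavenger receptors, Fc and complement receptors, inflammasome, co-signalling, retinoic acid and TGF-beta, transcription factors, T-bet and mixed cDC2 genes, NADPH oxidase, lysosome, lipids, glycolysis, eicosanoids, actin and adhesion, immediate early genes and sex-linked genes. Genes named are the 12 of largest ratio in each direction at 50 CPM or more (predicted, mitochondrial, ribosomal, histone and antigen receptor segment genes left out), up to 4 of largest ratio and 2 of highest expression per list, the sort genes, 5 leading genes per cluster, and in the mature contrast the 6 largest and 6 smallest ratios per library, the 6 largest differences and any gene 2-fold apart in opposite directions. A few further list members, named as examples of their list, were chosen after their values were seen. A gene that this rule names in the mature contrast is not reported here. A list's median log2 ratio was placed among 10000 random lists of its size matched on mean expression, as a description of these libraries.

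Cells of both libraries were clustered together with scanpy on 2000 highly variable genes after leaving out the 408 list genes that are not cell type markers, with 30 principal components, 20 neighbours and Leiden resolution 1. No batch correction was made, since library and sort are confounded. The naming rule was chosen after the data were seen. A marker counted when it was detected in 25% of a cluster's cells and 1.5-fold above other cells. A cluster with at least 5 cycling markers was cycling, and otherwise it took the class with most markers, at least 3, with ties settled by markers among its 10 leading genes. It stayed unnamed where another class led its own by 2 or more markers among those 10 genes, or where its median UMI count was more than 3 times below that of its library with none of its markers among them. Shares carry exact Clopper-Pearson intervals. For the shares of cells with cell cycle or Ccr7 UMIs, each cell was thinned to 2000 UMIs. The number of genes that independent lists would share is the product of the lists' sizes over the genes measured in both. Mature cells (cluster 9) were compared with other non-cycling dendritic clusters within each library at 20 CPM or more in 1 arm.

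The comparisons were tested on simulated Poisson counts drawn from the mean profile of the 2 whole libraries. The draws held no variation between cells, so they check the calculation and not how real counts spread over cells. For the library comparison, run on 6284 genes, 100 of 100 genes changed 3-fold and 100 of 100 changed 8-fold were recovered, 0 unchanged genes were called, and 94.8% of intervals held the true ratio. For the mature contrast in the cDC2 library, run on 4717 genes, 97 of 100 and 100 of 100 were recovered with 7 unchanged genes called, and 95.0% of intervals held the true ratio. A list of 15 raised genes reached percentile 100, and 20 unchanged lists lay between 4.93 and 96.7.

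In all, 30 alternatives fixed before the data were examined and 5 added afterwards were run, covering scaling (including edgeR's TMM factors), cell filters, doublet handling, cell types included, expression minimum, clustering, thinning and the definition of mature cells. Versions were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.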

Results

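Lung dendritic cells of C57BL/6 mice aged 8 to 10 weeks were profiled by droplet single-cell RNA sequencing in 2 libraries. Conventional dendritic cells (cDCs) are antigen-presenting cells of 2 main kinds, and the libraries held cells released with dispase and sorted by flow cytometry as cDC1 on the chemokine receptor XCR1 or as cDC2 on CD172a, the product of Sirpa. The question named by the design is how the steady-state transcriptomes of the 2 kinds compare. After filtering, the cDC1 library held 2570 cells with 34967686 unique molecular identifiers (UMIs) and the cDC2 library 2833 cells with 38479849 UMIs. The median cell carried 12860 and 12652 UMIs, respectively. With 1 library per sort there was no replicate check and no test was possible, so all intervals are 95% counting intervals for these libraries, and a 2-fold difference in CPM (UMIs of a gene scaled to the library total) is a rule of size, not a test.

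The genes of the proteins used for the sort followed the labels. Xcr1 (ENSMUSG00000060509; chromosome 9, 123852315 to 123862029, GRCm38) stood at 248 CPM in the cDC1 library and 4.86 CPM in the cDC2 library, a 51.1-fold difference (44.2 to 59.3). Sirpa (ENSMUSG00000037902; chromosome 2, 129592835 to 129632228) stood at 5.61 and 122 CPM, 21.8-fold higher in the cDC2 library (18.9 to 25.3). Genes outside the sort differed as widely. Gcsam was 203-fold higher in the cDC1 library (110 to 423; 52.6 against 0.260 CPM), and Irf8, the transcription factor that cDC1 cells depend on, was 26.7-fold higher (25.4 to 28.2; 1056 against 39.5 CPM). In the cDC2 library the sialic acid receptor gene Cd33 was 42.1-fold higher (32.5 to 55.6) and the transcription factor gene Zeb2 22.4-fold higher (20.5 to 24.6).

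Of 6617 genes at 10 CPM or more in at least 1 library, 518 (7.83%) were at least 2-fold higher in the cDC2 library and 367 (5.55%) in the cDC1 library, while 5732 lay within 2-fold. The 12 largest ratios toward cDC2 among genes at 50 CPM or more ran from Fn1 (fibronectin, 21.4-fold) to Cd33. Between them lay the interleukin-33 receptor gene Il1rl1 (29.5-fold), the lectin genes Clec10a (29.2-fold) and Mrc1 (27.4-fold), Emb (28.4-fold), Ms4a4c (28.4-fold), the NADPH oxidase gene Cybb (26.9-fold), Zeb2, Sirpa, the integrin gene Itgam (21.8-fold) and Fcrls (21.6-fold). Fn1 was seen in 11.97% of cDC2-library cells, against 92.3% for Cybb. The 12 largest ratios toward cDC1 ran from Agpat3 (21.2-fold) to Gcsam. The interferon-inducible genes Ifi205 (61.5-fold) and Ifi211 (46.6-fold), the mannose-6-phosphate receptor gene Igf2r (47.0-fold), the integrin gene Itgae (41.1-fold), the dead-cell receptor gene Clec9a (36.9-fold), the langerin gene Cd207 (34.0-fold), Cystm1 (23.9-fold) and Timeless (21.5-fold) were also among them. Counts of close paralogs, such as Ifi205 and Ifi211, Hspa1a and Hspa1b, or the Cd209 and Clec4a families, can be split by the counting and are uncertain to that extent.

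**Figure D1:**
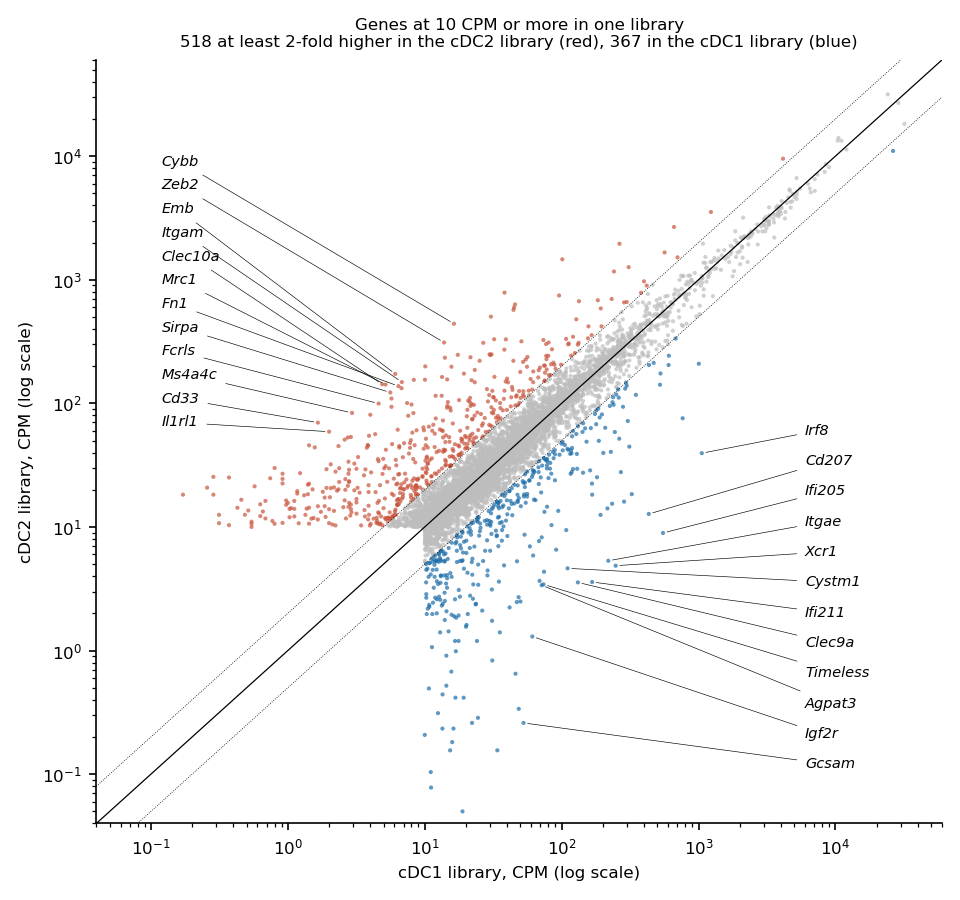
CPM of each gene at 10 CPM or more in 1 library, cDC1 library on the x axis and cDC2 library on the y axis, both on log scales, with the 2-fold lines dotted. Red points mark the 518 genes at least 2-fold higher in the cDC2 library, blue points the 367 higher in the cDC1 library, and labels the largest ratios among genes at 50 CPM or more, from Cd33 (42.1-fold) to Gcsam (203-fold). The point at the bottom edge had 0 UMIs in the cDC2 library and is drawn there because a log axis has no 0.

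The identity lists fixed beforehand separated by sort, and part of this follows from the sort itself. Of 16 measured cDC1 identity genes, 14 were at least 2-fold higher in the cDC1 library and 0 in the cDC2 library. Their median log2 ratio, cDC2 over cDC1, was -4.23, at percentile 0 of 10000 random lists matched on expression. Id2, a transcription factor gene of both kinds, differed by 1.73-fold only. Of 18 cDC2 identity genes, 14 were higher in the cDC2 library and 0 in the cDC1 library (median 3.71, percentile 100), among them Cd209d (88.9-fold), Cx3cr1 (32.0-fold), Mgl2 (14.5-fold, 1463 CPM) and S100a4 (7.38-fold, 1954 CPM). The list of T-bet-linked and mixed cDC2 subset genes, which shares 7 genes with other lists, had 6 of 9 higher in the cDC2 library and 0 in the cDC1 library, with Cd7 at 80.8-fold. Of 12 genes on the list named as shared conventional DC genes, 4 were higher in the cDC1 library and 1 in the cDC2 library. Ly75 (8.68-fold), Adam19 (2.66-fold), Jaml (2.59-fold) and the cystatin gene Cst3 (2.39-fold, 26339 against 11004 CPM) made up the former and Bcl11a (2.60-fold) the latter. Across the 30 lists, 16 medians reached percentile 99 or more (toward cDC2), 3 fell at percentile 1 or less (toward cDC1: cDC1 identity, the list of shared genes and MHC class I) and 11 lay between. The lists share genes, so these are not separate results. For example, 13 of the 18 cDC2 identity genes and 8 of the 20 lectin and scavenger receptor genes measured are also on other lists.

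Antigen presentation genes leaned toward different libraries by class, with 9 of 13 class II and 14 of 19 class I genes within 2-fold. Of 13 MHC class II presentation genes, 4 were at least 2-fold higher in the cDC2 library and 0 in the cDC1 library (median log2 0.36, percentile 99.7): H2-DMb2 (3.91-fold), the proteases Lgmn (3.64-fold) and Ctss (2.43-fold), and H2-Oa (2.08-fold). The highest-expressed members stayed within 2-fold, with Cd74 at 1.31-fold and H2-Eb1 at 1.33-fold. Of 19 MHC class I and cross-presentation genes, 5 were higher in the cDC1 library and 0 in the cDC2 library (median -0.26, percentile 0.18). They included the immunoproteasome gene Psmb9 (3.28-fold), Wdfy4, which is needed for cross-presentation (2.21-fold), Nlrc5 (2.18-fold) and the peptide transporter gene Tap2 (2.13-fold). B2m differed by 1.12-fold. Among 16 lysosomal proteases and inhibitors, 6 were higher in the cDC2 library, led by Ctsa (18.6-fold), Ctsd (4.77-fold) and Lamp1 (3.52-fold), and 2 in the cDC1 library, 1 of them Cst3. Of 11 NADPH oxidase and phagosome genes, 3 were higher in the cDC2 library, including Cybb and Rac2 (4.42-fold), and 2 in the cDC1 library, Dnase1l3 (10.5-fold) and Rab32 (3.42-fold).

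Lectin, scavenger, Fc and complement receptor genes were mostly higher in the cDC2 library, while the nucleic acid sensing and interferon-stimulated lists had as many members on each side. Of 20 C-type lectins and scavenger receptors, 12 were higher in the cDC2 library and 6 in the cDC1 library (median log2 2.90, percentile 100), with Cd163 (106-fold, on 6 UMIs in the cDC1 library), Clec4a3 (37.5-fold) and Cd209a (20.6-fold) on the cDC2 side and Clec9a and Cd207 on the cDC1 side. Of 9 Fc and complement receptor genes, 7 were higher in the cDC2 library and 0 in the cDC1 library, including Itgam, Fcgr3 (16.4-fold), the properdin gene Cfp (8.13-fold) and Fcer1g (4.83-fold). In the Toll-like receptor pathway (median 0.50, percentile 99.2), 2 of 8 genes were higher in the cDC2 library, Tlr2 (3.48-fold) and Cd14 (2.30-fold), and 1 in the cDC1 library, the double-stranded RNA receptor gene Tlr3 at 50.02 against 2.49 CPM (16.3- to 24.9-fold). Of 9 cytosolic nucleic acid sensing genes, 1 was higher on each side, Tmem173 (STING, 2.65-fold) in cDC2 and Ifi205 in cDC1, and of 6 interferon-stimulated genes (median -0.33, percentile 2.50) 2 were higher on each side, Isg15 (4.11-fold) and Ifi27l2a (2.27-fold) in cDC2, Mx1 (2.31-fold) and Stat2 (2.30-fold) in cDC1. Of 9 inflammasome genes, 4 were higher in the cDC2 library and 0 in the cDC1 library (median 0.85, percentile 99.97): Mefv (9.31-fold), Casp4 (6.35-fold), Il1b (2.87-fold, 1231 against 3532 CPM) and Casp1 (2.30-fold).

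**Figure D2:**
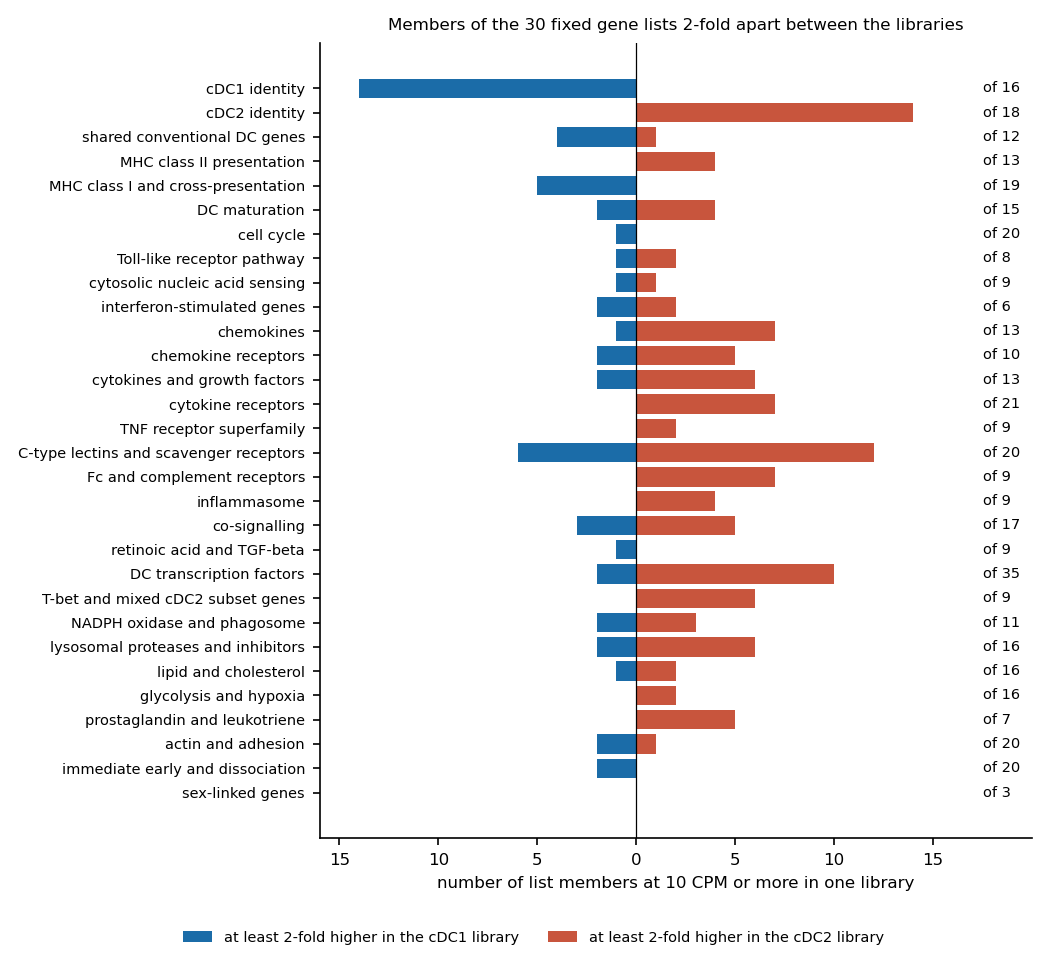
For each of the 30 gene lists, the number of measured members at least 2-fold higher in the cDC2 library (bars to the right) and in the cDC1 library (bars to the left). The cDC1 identity list has 14 members to the left and 0 to the right, the cDC2 identity list 14 to the right and 0 to the left.

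Secreted factors and their receptors differed in kind. The interleukin-12 subunit gene Il12b was 15.3-fold higher in the cDC1 library (14.03 to 16.7), whereas Areg (36.3-fold), Osm (22.1-fold) and Vegfa (7.93-fold) were higher in the cDC2 library. Of 13 cytokines and growth factors, 6 were higher in the cDC2 library and 2 in the cDC1 library. Of 13 chemokines, 7 were higher in the cDC2 library and 1 in the cDC1 library, led by Ccl9 (10.3-fold), Cxcl2 (7.12-fold), Cxcl1 (4.52-fold) and Ccl3 (4.41-fold), while Ccl17, the most abundant, differed by 1.504-fold. Of 10 chemokine receptors, 5 were higher in the cDC2 library, including Cx3cr1, Ccr1 (16.7-fold) and the lymph node homing receptor gene Ccr7 (3.01-fold), and 2 in the cDC1 library, Xcr1 and Cxcr3 (27.7-fold; 17.7 to 45.7). Of 21 cytokine receptors, 7 were higher in the cDC2 library and 0 in the cDC1 library, including Il1rl1, Csf1r (10.5-fold), Il17ra (7.13-fold) and Il2rg (6.99-fold). Of 9 TNF receptor superfamily genes, 2 were higher in the cDC2 library and 0 in the cDC1 library, Tnfrsf1b (2.61-fold) and Cd40 (2.47-fold). Of 15 maturation genes, 4 were higher in the cDC2 library, including Ccr7 and Cd274 (PD-L1, 2.55-fold), and 2 in the cDC1 library, Il12b and Cd200 (2.94-fold). Of 17 co-signalling genes, 5 were higher in the cDC2 library, with Lilrb4a at 6.53-fold, Cd200r1 at 5.31-fold and Pira2 at 3.07-fold, and 3 in the cDC1 library.

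Of 35 transcription factors, 10 were higher in the cDC2 library and 2 in the cDC1 library, with Zeb2, Cebpb (12.6-fold) and Spib (11.6-fold) against Irf8. Eicosanoid genes were cDC2-weighted: 5 of 7 prostaglandin and leukotriene genes were higher in that library and 0 in the cDC1 library, including the lipoxygenase gene Alox5 (33.3-fold), the inducible cyclooxygenase gene Ptgs2 (19.7-fold) and the prostaglandin-degrading Hpgd (15.3-fold). Of 16 lipid and cholesterol genes, 2 were higher in the cDC2 library, Lpl (12.2-fold) and Apoe (3.23-fold), and 1 in the cDC1 library, the scavenger receptor gene Cd36 (9.75-fold). Few members of the remaining lists differed. Of 20 cell cycle genes, 1 was higher in the cDC1 library, Cdk1 (2.45-fold), and 0 in the cDC2 library. Of 16 glycolysis and hypoxia genes, 2 were higher in the cDC2 library, Slc2a1 (2.72-fold) and Slc16a3 (2.31-fold), and 0 in the cDC1 library. Of 9 retinoic acid and TGF-beta genes, 1 was higher in the cDC1 library (Itgae) and 0 in the cDC2 library. Of 20 actin and adhesion genes, 1 was higher in the cDC2 library (Itgam) and 2 in the cDC1 library, Cadm1 (15.2-fold) and Epcam (3.31-fold). Of 20 immediate early and dissociation genes, 0 were higher in the cDC2 library and 2 in the cDC1 library, the heat shock genes Hspa1a (2.96-fold) and Hspa1b (2.15-fold). None of 3 sex-linked genes measured differed by 2-fold, with the largest ratio 1.23 for Ddx3y.

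Restricting both libraries to clusters named as dendritic cells kept most of these differences. It left out 54 cells (2.10%) of the cDC1 library and 589 (20.8%) of the cDC2 library, 308 of them in the unnamed cluster 7, where the dendritic growth factor receptor gene Flt3 stood at 120 CPM and the dendritic transcription factor gene Zbtb46 at 51.1 CPM, against 10.3 and 28.0 CPM in cluster 11 of that library. With cluster 7 kept in, 478 and 387 genes were higher in the cDC2 and cDC1 library. Without it, of 6542 genes measured, 477 were higher in the cDC2 library and 396 in the cDC1 library, and 453 and 359 of these were the same genes as before. Several genes known from macrophages moved, chosen here after their values were seen. Apoe went from a log2 ratio of 1.69 to -0.13 and, with cluster 7 kept in, to 0.50. Lpl went from 3.61 to 1.64, the phospholipase gene Pla2g7 from 2.80 to 1.18, the lysozyme gene Lyz2 from -0.09 to -0.98 and Cd36 from -3.29 to -4.63. Chemokines higher in the cDC2 library then numbered 4 of 11, with a list median of 0.88 in place of 1.51. Cluster 11 held 5271 of the 10458 Cxcl2 UMIs and 346 of the 507 Cxcl1 UMIs of the cDC2 library, and among dendritic clusters the log2 ratios were 2.73 in place of 2.83 and 1.85 in place of 2.18.

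Joint clustering that left out the 408 list genes outside the cell type markers gave 17 clusters, numbered by size, and the sort sets their shares. List genes that are also markers, such as Xcr1, Irf8, Sirpa and Ccr7, could take part in it. In the cDC1 library, 82.7% of cells (81.2 to 84.1) fell in clusters 3, 4, 5, 10 and 12, whose markers were cDC1-like, with 721, 598, 591, 162 and 53 cells. The cDC2 library had 5, 5, 5, 5 and 25 cells in the same clusters. In the cDC2 library, 63.6% of cells (61.8 to 65.4) fell in cDC2-like clusters 1 (946 cells, 33.4%) and 2 (857 cells, 30.3%), where the cDC1 library had 7 and 28 cells. Clusters 2, 5 and 12 had more markers of another cell type than of their own among their 10 leading genes, so these populations are compared by cluster number, and sums over dendritic clusters include them. Cycling cells formed cluster 8 in the cDC1 library (226 cells, 8.79%) and cluster 6 in the cDC2 library (319 cells, 11.3%, beside 16 in the cDC1 library). Mature DC-like cells of cluster 9, led by the actin-bundling gene Fscn1 with Apol7c, Cacnb3, Nudt17 and H2-M2, made up 4.44% of the cDC1 library (114 cells; 3.67 to 5.30) and 2.68% of the cDC2 library (76 cells; 2.12 to 3.35). At a clustering resolution of 2 the order turned, with 5.37% of the cDC1 library and 16.7% of the cDC2 library.

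Clusters left unnamed held 1.36% of the cDC1 library (35 cells) and 19.1% of the cDC2 library (541 cells), a share set by a naming rule chosen after the data were seen. It ranged from 0% to 6.23% and from 8.30% to 18.2% under the alternatives, and in 6 of 10 alternatives the cluster led by Retnla and Fn1, like cluster 11, was named interstitial macrophage-like. Cluster 7 (308 cells, 10.9% of the cDC2 library) was led by Cd7, Plac8, Ifitm6, Ms4a6b and Ifitm3 and had 0 cells in the cDC1 library, which allows up to 0.117% by a floor of 3 cells and 0.143% by the exact interval. Cluster 11 (154 cells, 5.44%, beside 12 in the cDC1 library) was led by Retnla, Fn1, Lpl, F13a1 and C1qb, genes of macrophages and monocytes. By marker count cDC2 came first there with 6, before interstitial macrophage with 5, and its leading genes left it unnamed. Cluster 13 (69 cells, 2.44%, beside 3) was led by the neutrophil genes S100a9, S100a8, Retnlg, Slpi and Lcn2. It had 10 nonclassical monocyte markers against 9 neutrophil markers. At resolution 2 there were separate nonclassical monocyte-like (40 cells) and neutrophil-like (29 cells) clusters in the cDC2 library. Cluster 15 (20 and 10 cells) was led by Gm42418 and mt-Nd6 at low depth. It had 8 cDC1 markers, but its low depth and its leading genes left it unnamed. B cell-like cells numbered 36 in the cDC2 library and 4 in the cDC1 library, NK cell-like cells 6 and 10, and fibroblast-like cells 6 and 5. A cluster found almost wholly in 1 library can reflect that library as well as a cell type.

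**Figure D3:**
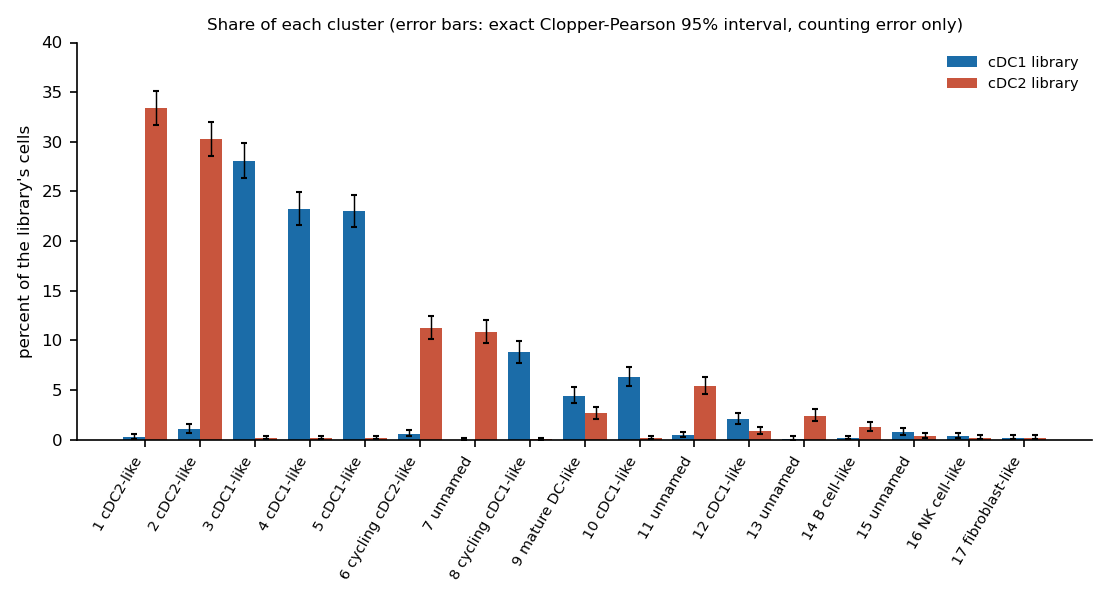
Share of each library's cells in each of the 17 clusters, in percent, with exact 95% binomial intervals. Clusters 1 and 2 hold 33.4% and 30.3% of the cDC2 library, and clusters 3, 4 and 5 hold 28.1%, 23.3% and 23.0% of the cDC1 library.

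The share of cells with cell cycle transcripts was close in the 2 libraries. With each cell thinned to 2000 UMIs, 18.0% of cDC1-library cells (462 of 2563; 16.6 to 19.6) and 19.9% of cDC2-library cells (562 of 2821; 18.5 to 21.4) held at least 2 UMIs of cell cycle genes. With 1 library per sort, this difference was not tested. In mature DC-like cells, which should not cycle, the same measure gave 7.02% (8 of 114, median 13014 UMIs before thinning) and 10.5% (8 of 76, median 10392 UMIs), against medians of 12869 and 12682 UMIs over all thinned cells. Without thinning the shares were 72.0% and 71.2%. Thinning left out 7 and 12 cells below 2000 UMIs.

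Ccr7 transcripts were far more widespread among cDC2-sorted cells. After thinning, 41.7% of cDC2-library cells (1176 of 2821; 39.9 to 43.5) and 10.3% of cDC1-library cells (265 of 2563; 9.19 to 11.6) carried at least 1 Ccr7 UMI. As background, 1.18% (7 of 593, median 12639 UMIs) were positive in cluster 4 of the cDC1 library. In cluster 13 of the cDC2 library, which mixed neutrophil and nonclassical monocyte markers, 6.15% (4 of 65, median 7241 UMIs) were positive. Other non-dendritic clusters of the cDC2 library were not used as background, which may therefore be higher. Most positive cells of the cDC2 library lay outside the mature cluster. Cluster 2 was positive in 70.2% (67.0 to 73.3) of cells and cluster 1 in 22.9% (20.2 to 25.7), while the mature cluster 9 was positive in 98.2% and 98.7% of cells of the cDC1 and cDC2 libraries. Among 36 B cell-like cells of the cDC2 library, 69.4% were positive. Without thinning the shares were 18.2% in the cDC1 library and 63.8% in the cDC2 library.

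Genes that set mature cells apart from other dendritic cells overlapped in part between the sorts. Among 253 list genes that took no part in the clustering and were measured in both libraries, 67 were at least 2-fold higher in mature cells of the cDC1 library, 46 in those of the cDC2 library and 34 in both, where independent lists of these sizes would share 12.2. At least 2-fold lower were 52, 42 and 30, where independent lists would share 8.63, and 208 genes had the same sign. Mature cells of both libraries came from the joint cluster 9, so overlap above independence follows in part from how the cells were grouped. Apol7c was 847-fold higher in mature cells of the cDC1 library (442 to 1865) and 1618-fold higher in those of the cDC2 library (846 to 3556). The chemokine gene Ccl5 was 313- and 74.7-fold higher, the TGF-beta-activating integrin gene Itgb8 179- and 63.7-fold, the costimulatory receptor gene Tnfrsf9 130- and 90.5-fold, the fatty acid binding protein gene Fabp5 129- and 63.3-fold and the guanylate-binding protein gene Gbp2 120- and 31.3-fold. Fabp4 was 144-fold higher in the cDC2 library (80.9 to 276) and below the expression minimum in the cDC1 library. This contrast set 114 mature against 2160 other non-cycling dendritic cells in the cDC1 library, and 76 against 1848 in the cDC2 library.

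By list, 7 of 11 maturation genes rose by the size rule in both libraries and 0 fell in both, among them the NF-kB subunit gene Relb (10.9- and 6.79-fold), Cd274 (10.9- and 4.13-fold) and Il12b (12.7- and 51.3-fold). So did 5 of 7 TNF receptor superfamily genes, 4 of 6 interferon-stimulated genes, 4 of 18 MHC class I genes, including Psme2 (4.34- and 4.06-fold), and 5 of 13 lipid and cholesterol genes. The retinoic acid synthesis gene Aldh1a2 was 24.6- and 28.9-fold higher. In the other direction, 4 of 12 MHC class II presentation genes were lower in mature cells of both libraries, H2-DMa (6.55- and 3.15-fold), H2-DMb1, H2-Oa and H2-Ob, as were 4 of 5 Fc and complement receptor genes and 4 of 25 transcription factors (Bach2, Cebpa, Runx1 and Ahr). Among the deepest falls in the cDC1 library were those of March1 (13.3-fold, 4.52 to 64.4, on 3 UMIs in mature cells), the leukotriene gene Alox5ap (12.2-fold), Tnfsf13b (11.7-fold), Itgb7 (7.14-fold) and Nlrp3 (7.04-fold). Those in the cDC2 library were of Hpgd (5.72-fold), Bach2 (3.97-fold), Vegfa (3.92-fold), Ccr1 (3.89-fold), Cd180 (3.86-fold) and H2-Ob (3.80-fold).

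The ratios of the 2 sorts parted at a few genes. Tmem176a was 30.5-fold higher in mature than in other cells of the cDC1 library and 1.18-fold in the cDC2 library, and Tmem176b (23.1- and 1.36-fold), Ccl9 (15.1- and 1.17-fold) and the interleukin-1 antagonist gene Il1rn (51.0- and 2.51-fold) were likewise further apart in the cDC1 library. The DNase gene Dnase1l3 showed the converse, 1.39-fold (1.16 to 1.64) and 28.3-fold (19.9 to 40.3). These ratios depend on the level in the other cells of each library. Tmem176a and Tmem176b are on the cDC2 identity list, while Ccl9 was higher in the whole cDC2 library and Dnase1l3 in the whole cDC1 library. In other cells of the cDC1 library Tmem176a, Tmem176b and Ccl9 stood at 16.7, 19.7 and 9.84 CPM. Ratios that part thus do not show that levels in mature cells differ. Only Ptgs2 was at least 2-fold apart in opposite directions, 4.34-fold higher in mature cells of the cDC1 library (2.89 to 6.34) and 3.19-fold lower in those of the cDC2 library (2.49 to 4.15). These differences between libraries were not tested. Without 22 mature cells of the cDC1 library that a finer clustering set apart, Ptgs2 stood at 3.21 CPM in mature and 5.06 CPM in other cells of that library, and Il1rn at 8.84 CPM, below the expression minimum, and 22.5-fold (8.86 to 57.3). At a finer clustering resolution, where 472 cDC2-library cells counted as mature, or with mature cells defined by at least 2 Ccr7 UMIs, the genes higher in both libraries numbered 14 and 9 and those lower in both 8 and 5, and Ptgs2, Nlrp3 and Vegfa were no longer lower in mature cells of the cDC2 library.

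**Figure D4:**
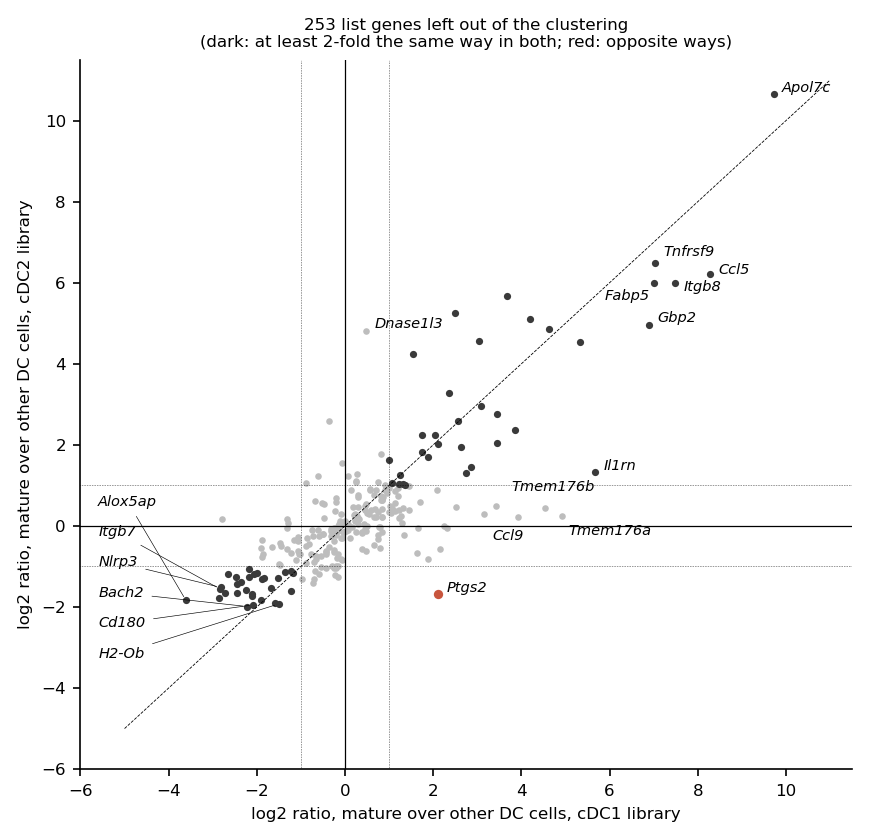
Log2 ratio of mature over other dendritic cells in the cDC1 library (x axis) and in the cDC2 library (y axis) for 253 list genes left out of the clustering, with the 2-fold lines dotted and the line of equal ratios dashed. Dark points were at least 2-fold apart the same way in both libraries (34 higher, 30 lower), and the red point is Ptgs2, at 2.12 and -1.67.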

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

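The 3 tests in this part were chosen only after the result was seen. Ptgs2 was singled out because mature cells of both sorts moved in opposite directions. The log2 ratio of mature over other dendritic cells was 2.12 in the cDC1 library and -1.67 in the cDC2 library, a difference of -3.79 that was not itself tested, since each sort has 1 library.

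Ptgs2, Tmem176a, Tmem176b and Ccl9 stood higher in mature than in other dendritic cells of the cDC1 library, and a candidate explanation is mature cells of the cDC2 kind in the XCR1 sort. It is argued against for Tmem176a, Tmem176b and Ccl9, which stayed high (452, 405 and 120 CPM, the lowest of the 3 ratios 12.2-fold, 9.90 to 14.9) without the 22 of 114 mature cells that a finer clustering put with 68 of the 76 of the cDC2 library. Doublets of mature with cDC2 cells are argued against for these 3 genes, since 7 cDC2 genes (Sirpa, Zeb2, Cybb, Itgam, Clec10a, Cd209a and Mgl2) gave 58 UMIs in the other 92 cells (upper bound 75.0) where such doublets would need 708. For Ptgs2 the explanation stays open: the 92 cells had 0.635 of the level of other dendritic cells (0.171 to 1.66), and the 22 cells had Xcr1 at 72.1 CPM (45.2 to 109), against 82.0 CPM in the 92 and 0 UMIs in mature cells of the cDC2 library, but all 22 Xcr1 UMIs lay in 3 cells with 0 Ptgs2 UMIs, while the 19 cells without Xcr1 held the 30 Ptgs2 UMIs, 4 UMIs of 5 cDC1 genes (Xcr1 among them) where the level of the 92 would give 106.1, Irf8 at 190.3 CPM against 173 CPM in the 68 and 932 CPM in the 92, Sirpa at 77.9% of its level in the 68, and the 7 cDC2 genes at 45.8% of their level in the 68 cells (160 UMIs, upper bound 186.8, where 349 would be needed), with 0 Cd209a UMIs where 58.3 would be needed. Of the 106.1, Xcr1 makes up 18.95, and its count of 0 was fixed by the choice of the 19 cells. The rise of Ptgs2 in mature cells of the cDC1 library thus rested on the 19 cells, which held few cDC1 transcripts. The interval of the 92 cells (0.171 to 1.66) argues against a 2-fold rise in mature cells like these 92, while the kind of the 19 cells stays open. A biological difference between mature cells of the sorts also stays open and untested.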

How the results depend on the processing

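Of the alternatives below, 5 were chosen after the data were seen: leaving out the 5% of cells with the highest doublet scores (for gene ratios and for shares), leaving out only clusters of other cell types, taking mature cells from the main piece of the mature cluster, and taking other dendritic cells of the library's own kind. The causes were not tested unless stated. No paired analysis was possible because each sort has 1 library and the sorts share replicate number 1 alone.

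Gene counts of 518 and 367 (cDC2 and cDC1 library) stayed within 1.5 times in 13 of 16 alternatives. They became 223 and 143 at a 50 CPM minimum, 2072 and 1582 with 3 UMIs as the only minimum and 241 and 137 at 4-fold, as these rules take in fewer or more genes. No scaling moved the split by over 10 percentage points (58.5% toward cDC2, 55.9% with TMM). The log2 ratio of Sirpa (4.45) was 4.75 among dendritic clusters, 7.93 for cDC1-like against cDC2-like clusters, 5.38 without mature and cycling clusters and 4.71 with cluster 7 kept beside the dendritic clusters. That of Xcr1 (-5.67) was -5.19 with thinned cells, -6.07 for cDC1-like against cDC2-like clusters and -5.40 without mature and cycling clusters. Apoe reversed to -0.13 among dendritic clusters, -0.23 for cDC1-like against cDC2-like clusters and -0.23 without mature and cycling clusters, and was 0.50 with the unnamed cluster 7 kept beside the dendritic clusters. Of the other values of single gene ratios between libraries under the alternatives, 1418 stayed inside the counting interval and 620 moved past it without a called ratio changing sign.

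The cDC1-like share of the cDC1 library (82.7%) was 79.0% without a cell filter. The cDC2-like share of the cDC2 library (63.6%) was 66.5% at resolution 0.5, 52.3% at resolution 2, 67.4% with 1000 variable genes, 66.5% with each library clustered alone, 65.7% with doublet calls kept, 67.3% without a cell filter, 66.2% with the stricter filter and 66.6% without the highest doublet scores. The mature share of the cDC1 library (4.44%) was 5.37% at resolution 2 and 7.43% clustered alone. That of the cDC2 library (2.68%) was 16.7% at resolution 2 and 2.01% with the stricter filter, so the order of the sorts turned at resolution 2. Unnamed cells of the cDC2 library (19.1%) were 16.4% at resolution 0.5, 8.65% at resolution 2, 8.30% with 1000 variable genes and between 10.9% and 18.2% otherwise. Cycling cDC1-like cells were 10.7% (8.79%) with list genes used in the clustering, and cycling cDC2-like cells 9.82% (11.3%) without a filter.

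Cells with cell cycle UMIs were 43.6% and 44.8% at 1 UMI, 10.5% and 12.4% at 3 UMIs, 9.65% and 10.7% thinned to 1000 UMIs, and 72.0% and 71.2% without thinning (cDC1 and cDC2 library). Ccr7-positive cells were 7.10% and 28.1% at 2 UMIs, 8.02% and 31.6% thinned to 1000 UMIs, and 18.2% and 63.8% without thinning, higher in the cDC2 library each time.

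In the mature contrast, the 34 list genes higher and 30 lower in both libraries became 14 and 8 at resolution 2 and 9 and 5 with mature cells defined by 2 Ccr7 UMIs, which place 472 and 1300 cells of the cDC2 library among the mature. Reversed log2 ratios in the cDC2 library at resolution 2 were 0.31 for Ptgs2, 0.14 for Nlrp3 and 1.40 for Vegfa. With Ccr7-defined cells they were 0.54 for Ptgs2, 0.33 for Nlrp3, 0.26 for Cd180 and 0.97 for Vegfa. Ptgs2 in the cDC1 library turned to -0.65 with mature cells of the main piece alone. Mature cells of the cDC2 library hold 944917 UMIs, which limits the precision of single genes there.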

Other observations

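The contrasts between clusters, the genes named in them and the 5 tests of explanations in this part were chosen only after the data were seen. Clusters were formed without the list genes compared here unless stated, and ratios carry counting intervals for these libraries only.

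Within the cDC1 library, cluster 3 had 13 of 226 list genes at least 2-fold higher and 5 lower than the other non-cycling cDC1-like clusters, and no list was tested for enrichment. Among the 13, the costimulatory ligand gene Tnfsf9 was 9.16-fold higher (8.07 to 10.4), the adhesion gene Icam1 5.62-fold, Tnf 5.08-fold, the NF-kB inhibitor gene Nfkbia 4.32-fold and Il12b 3.81-fold. Cluster 4 had the converse, with Il12b 32.7-fold lower (24.8 to 44.1), the chemokine gene Ccl17 7.96-fold lower and Cd40 6.41-fold lower. Cluster 5 carried more of the lipopolysaccharide co-receptor gene Cd14 (3.36-fold), the GM-CSF receptor genes Csf2rb2 (3.27-fold) and Csf2rb (2.63-fold), the langerin gene Cd207 (3.11-fold) and the apoptotic cell receptor gene Timd4 (2.25-fold). Cluster 10 was high in the heat shock genes Hspa1b and Hspa1a (12.1-fold each) and Dnajb1 (9.10-fold), together with Cxcr3 (4.90-fold) and the class II transactivator gene Ciita (3.29-fold), and low in Il12b (32.9-fold) and Cd80 (12.7-fold). The 53 cells of cluster 12 summed to more Cd8a (59.2-fold, 30.9 to 117, from 12 of the cells), Cxcl10 (22.9-fold) and the interferon-stimulated genes Rsad2 (22.5-fold) and Irf7 (12.3-fold), and less Ccl17 (23.0-fold) and Cd207 (21.0-fold).

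Within the cDC2 library, cluster 1 differed from cluster 2 by more Hspa1b (11.4-fold), Egr1 (7.99-fold), the haemoglobin scavenger receptor gene Cd163 (4.60-fold) and the chemokine gene Ccl4 (3.83-fold), whereas cluster 2 had more Cxcl2 (5.15-fold), Csf2rb2 (3.05-fold), Ccl17 (2.96-fold) and Cd274 (2.82-fold). Cluster 7, which the markers left unnamed, had more Cd7 (48.7-fold, 38.7 to 61.8), Irf7 (16.8-fold), the transcription factor genes Spib (3.92-fold) and Klf2 (3.12-fold), and less Ccl17 (11.6-fold), Cd14 (4.55-fold) and Id2 (4.15-fold) than clusters 1 and 2. Cluster 11 combined Pla2g7 (141-fold, 92.9 to 222), the neutrophil-attracting chemokine genes Cxcl3 (63.1-fold), Cxcl1 (25.6-fold) and Cxcl2 (19.5-fold), Il1rn (25.2-fold), Cebpb (18.8-fold) and Lyz2 (11.8-fold) with less Kit (11.3-fold lower), H2-Oa (8.07-fold lower) and the dendritic growth factor receptor gene Flt3 (7.67-fold lower), with 59 of 288 list genes at least 2-fold higher and 23 lower.

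Irf8, a cDC1 marker that took part in the clustering, was 5.58-fold higher in mature than in other dendritic cells of the cDC2 library (196 CPM, 169 to 226, against 35.1 CPM). Those other cells include the 45 cDC1-like cells of that library, and clusters 1 and 2 alone stood at 9.07 CPM, so the ratio depends on this mixture. Mature cDC1 cells in the CD172a sort are argued against, since giving this Irf8 they would bring 84.8 UMIs of Xcr1, Clec9a, Itgae, Ifi205 and Gcsam, and 6 were counted (upper bound 13.1). Free RNA is argued against because Irf8 was 21.6-fold above its level in clusters 1 and 2 of the same library. A biological difference of mature cDC2 cells stays open and was not tested.

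Cluster 12 held 25 cells of the cDC2 library although cDC1 genes mark it. It made up 55.6% of the cDC1-like cells there (25 of 45; 39.997 to 70.4) and 2.49% in the cDC1 library (1.87 to 3.25), which argues against an even leak of XCR1-sorted cell types, although a selective leak of cells with little XCR1 stays open, as Xcr1 was at 73.7 CPM (47.2 to 110) in these cells and 296 CPM (259 to 337) in the 53 of the cDC1 library. Doublets of a cDC1 and a cDC2 cell are argued against by 7 cDC2 genes at 6.00% of their level in cDC2-like cells (upper bound 7.50%), of which Cd209a gave 52 of 77 UMIs and stood at 160 CPM (119 to 209) in 10 of the 25 cells, against 1212 and 623 CPM in clusters 1 and 2 and 0 UMIs in the 53 cells of the cDC1 library. Free RNA is argued against by Irf8 at 1370 CPM (lower bound 1246), against 39.5 CPM in the whole library. Xcr1, Irf8, Sirpa, Itgam, Clec10a, Cd209a and Mgl2 are cell type markers that could take part in the clustering. Their levels in cluster 12 thus follow in part from how the cells were grouped, which weakens the checks for doublets and free RNA. No biological explanation was tested.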
